A study of Sus scrofa with 30 samples.

How the data were processed

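Gene expression was measured in adipose tissue, described in the labels as subcutaneous, from 30 pigs of the Basque and Large White breeds, weighing 35 kg or 145 kg alive. The series' design text speaks of muscles, whereas every sample label names adipose tissue, and the sample labels are followed here. Each animal was hybridised once, on a 2-colour Agilent array. Per the labels, 350 ng of total RNA was labelled, each animal's RNA carried Cy3, and a reference made from equal parts of all 30 RNAs carried Cy5. No dye swap is described, so any dye effect is shared by all arrays and drops out of differences between groups.

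The deposited table holds 1 value per feature and array on a log scale, read here as log2, for 8369 features with 0 missing values, as a ratio between an animal and the pool. Per the submitters' processing notes, the tools were R 2.10.0 and limma. The background correction, the normalization and the filter that left 8369 features are not given in the sources used here. Feature numbers run from 6 to 15738 and are the sole row names. No table used here pairs them with probes or genes, so no gene is named, and gene lists and cell type markers fixed before the data were examined could not be tested. Results are therefore counted in features. Features are not genes: 363 of them (4.34%) correlated at r of at least 0.98 with another feature over the 30 arrays, as repeated spots or probes of 1 transcript would.

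Neither the log base nor the direction of the ratio is stated. Because the pool is the mean of the 30 RNAs, a log2 ratio of sample to pool should have a mean that falls with its variance, with a slope of -0.347, and the opposite ratio should give 0.347. The observed slope across features was -0.298 (95% bootstrap interval over features -0.321 to -0.279). Sample over pool is thus the likely direction, on the basis of the values alone. The interval does not reach -0.347, so the slope settles the sign better than the base of the logarithm, and base 2 is likely rather than known. All signs and folds rest on these readings. The skew of muscle, blood and skin genes, planned as a second basis, could not be run without gene names.

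The deposited values were used without further normalization. A model of 4 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and 4 comparisons and the breed by live weight interaction were tested, 2-sided, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. Design and alternatives were fixed before the data were examined, for genes; features took their place. The rule for named genes needed symbols. Instead, the features with the largest difference each way for breed at 145 kg and for live weight in Basque pigs are described, and at most 2 rising and 2 falling are given by number. Feature 11529 was chosen after its values were seen. Group means of principal components and of feature sets were compared by permutation, exact where a group had under 10 animals and with 100000 resamples otherwise (scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15). Plots were drawn with matplotlib 3.10.9.

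The code was tested on simulated values for the 8369 features in which 200 were changed. At a log2 change of 0.5, 50% were recovered for breed at 145 kg, 31% for breed at 35 kg, 32% for live weight in Basque and 51% for live weight in Large White pigs. At a log2 change of 1 the shares were 94%, 74%, 84% and 87% in the same order. False calls made up 7.10%, 1.87%, 2.52% and 3.50% of the calls. Both live weight comparisons have the same group sizes and a shared spread estimate, so their shares differ through the features drawn, not through power. Simulated features were independent, whereas many real features vary together and a larger share of them was called. The shares are thus a check of the code, not error rates of the real lists.

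The labels give each array a chip number. Each of the 5 chips held 6 arrays, with 1 animal of each breed at 35 kg and 2 of each breed at 145 kg, so chip was balanced over the groups. At 35 kg the replicate number and the chip are the same pairing. After group means, chip took 11.8% of the variance over 4 degrees of freedom, 36 features passed the threshold for chip, and the consensus correlation within a chip was 0.016. Chip as a block and within-chip values are given where they change a count. Of the 30 arrays, 20 had a median within 0.00300 of 0 and 10 had a median below -0.01, among them all 6 of chip 5 (against 4 of 24 elsewhere, Fisher's exact p = 3.54e-04). Group ranges of the array medians were -0.0149 to -3.18e-05 (Basque 35 kg), -0.0625 to 1.41e-04 (Large White 35 kg), -0.0918 to -1.23e-04 (Basque 145 kg) and -0.181 to 6.02e-04 (Large White 145 kg). Why some arrays are off centre is not known.

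Alternatives were chip as a fixed or random block, the compared groups alone in the fit, quantile normalization, median centring, scaling to 1 median absolute deviation, robust eBayes, array weights, a filter on low variance, stricter thresholds, unmoderated least squares and each animal left out. Leaving out doubted arrays, and the replicate number as a block, were added after seeing the data. With arrays, the number of animals limits the precision; signal over background is not in the values used here.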

Results

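The data are log2 ratios of 8369 array features in adipose tissue of 30 pigs. The groups are 5 Basque and 5 Large White pigs at 35 kg, and 10 Basque and 10 Large White pigs at 145 kg live weight. Each animal is a biological replicate on 1 array, set against a pool of all 30 RNAs. The design asks how adipose gene expression differs between the breeds at each live weight and between live weights in each breed. Features carry numbers only, so the results are given for features and for sets of features that vary together.

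Live weight and breed formed the leading axes of variation. The first principal component held 22.0% of the variance and separated live weights: mean scores were 16.3 ± 5.07 (SD, n = 10) in Basque and 9.17 ± 6.46 (SD, n = 10) in Large White pigs at 145 kg, against -25.9 ± 4.05 (SD, n = 5) and -25.2 ± 7.13 (SD, n = 5) at 35 kg. The exact permutation test gave p = 6.66e-04 in each breed, the smallest it can give, with an adjusted p of 0.00178 over 8 tests. Breeds also differed on it at 145 kg, by 7.17 (permutation test, adjusted p = 0.0225). The second component held 16.4% and separated breeds, by -26.0 at 145 kg (permutation test, adjusted p = 6.40e-04) and by -30.1 at 35 kg (exact permutation test, adjusted p = 0.0159). One Large White pig of 145 kg, replicate 8, lay at -15.4 on this component, where the other 9 lay between 4.06 and 33.0. Of the total variance, live weight took 20.1%, breed 13.0% and their interaction 3.49%, with 1 degree of freedom each, and chip 11.8% over 4. The remaining 51.6% lay between animals and includes array noise, as each animal had 1 array. Per degree of freedom, chip took 2.95% and the interaction 3.49%, against 2.35% for the remainder.

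**Figure D1:**
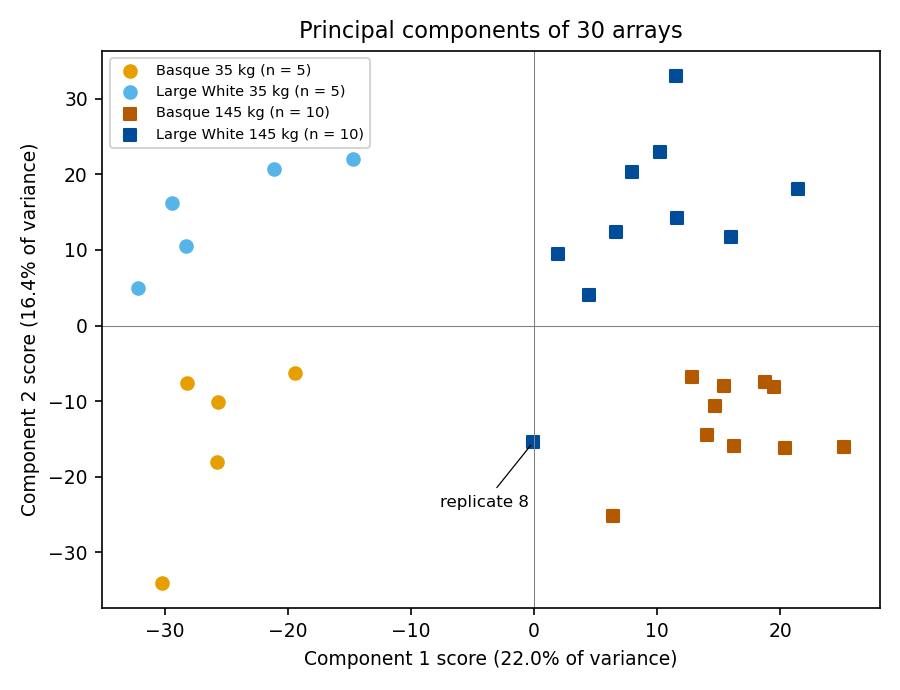
Scores of the 30 arrays on the first (x axis, 22.0% of variance) and second (y axis, 16.4%) principal components, in arbitrary units, with 1 point per animal, coloured by group and with squares for 145 kg. Live weights part along x and breeds along y, except for Large White 145 kg replicate 8 at -15.4 on y.

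Between breeds at 145 kg, 1467 features (17.5%) differed at an adjusted p under 0.05 in limma, 826 higher and 641 lower in Basque pigs. Most differences were small, with a median absolute log2 difference of 0.44 among them, and 81 features were at least 2-fold higher and 52 at least 2-fold lower in Basque pigs. Feature 11584 had the largest decrease and was 6.51-fold lower in Basque pigs (log2 difference -2.70, SE 0.35, limma adjusted p = 4.77e-06), with means of -1.31 ± 0.46 (SD, n = 10) in Basque and 1.39 ± 0.89 (SD, n = 10) in Large White pigs. Feature 7894 had the largest increase and was 5.39-fold higher in Basque pigs (log2 difference 2.43, SE 0.51, limma adjusted p = 0.00165), with means of -0.15 ± 1.07 (SD, n = 10) and -2.58 ± 1.58 (SD, n = 10); the call was lost when the 10 arrays with a median below -0.01 were left out (1.59). Both features kept their direction in all 5 chips. The count fell to 658 without those 10 arrays and to 907 without chip 5, and quantile normalization turned the balance to 812 higher and 827 lower.

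Between breeds at 35 kg, 728 features (8.70%) differed, 380 higher and 348 lower in Basque pigs, with a median absolute log2 difference of 0.60. At least 2-fold differences were found for 101 higher and 49 lower features. The largest increase was 32.7-fold (log2 difference 5.03, SE 0.73, limma adjusted p = 1.08e-04). Feature 11584 again had the largest decrease (log2 difference -2.24, SE 0.49, limma adjusted p = 0.00541), with means of -2.19 ± 1.29 (SD, n = 5) in Basque and 0.046 ± 0.62 (SD, n = 5) in Large White pigs; its call was lost without chip 5 (-1.91) and without the 10 off-centre arrays (-1.86). Feature 7894 had a log2 difference of 1.91 that did not pass (SE 0.72, limma adjusted p = 0.0961), with the same sign in all 5 chips. It passed with the replicate number, here the same as the chip, as a block in a fit of the 35 kg animals (limma adjusted p = 0.0490), with those animals alone (0.0229) and with array weights (0.0493), and over all alternatives its adjusted p lay between 0.0229 and 0.377. Quantile normalization gave 424 features, of which 41.5% were higher in Basque pigs against 52.2% with the deposited values, and median centring gave 352 higher and 364 lower. The count also fell to 438 and 463 without Basque 35 kg replicate 4 or 5, to 413 and 470 without Large White 35 kg replicate 1 or 5, and to 465 without chip 5, and it rose to 1370 with array weights (745 of them higher).

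Feature 11529 parted the breeds without overlap over all 30 animals: the highest Basque value was -0.011 and the lowest Large White value 1.02. It was 5.20-fold lower in Basque pigs at 145 kg (log2 difference -2.38, SE 0.14, limma adjusted p = 1.52e-12) and 4.20-fold lower at 35 kg (log2 difference -2.07, SE 0.20, limma adjusted p = 2.58e-07), in all 5 chips. In total 2 features were higher and 4 lower in all 15 Basque than in all 15 Large White pigs, where chance gives 1.08e-04 features. Breed differences at the 2 live weights, which come from separate animals, were correlated across features (r = 0.56, jackknife SE over animals 0.074; features are not independent replicates). Both lists shared 185 features higher and 146 lower in Basque pigs, against 37.5 and 26.7 for independent lists, and 3 features had opposite signs.

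**Figure D2:**
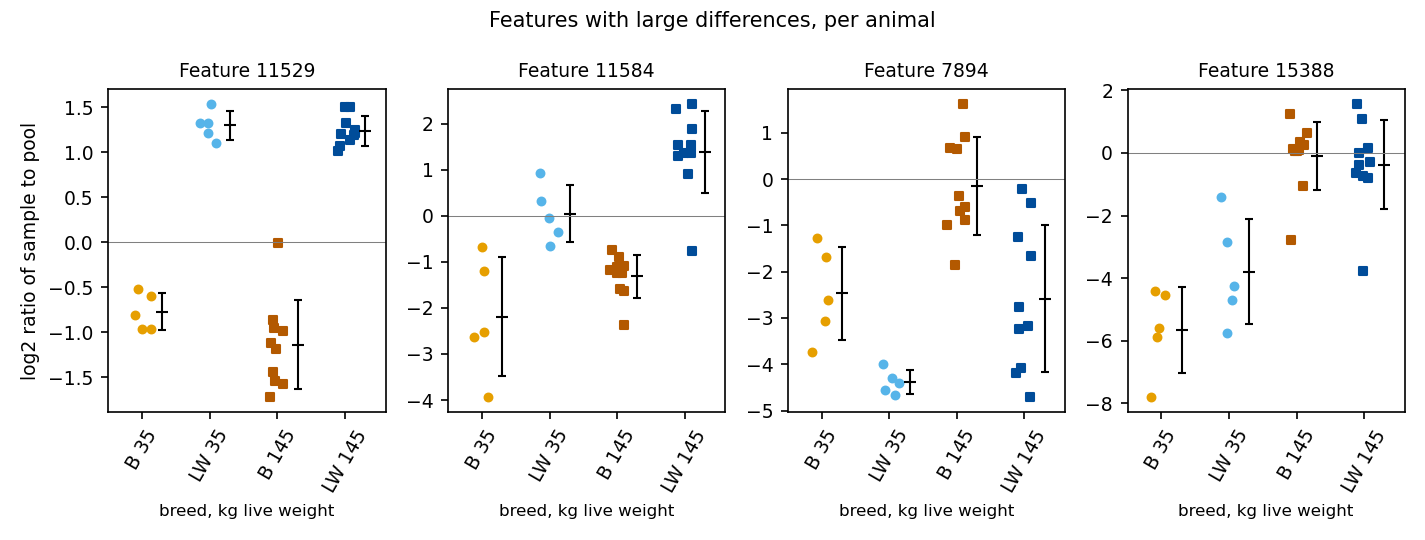
Log2 ratio of sample to pool (y axis) in each animal by group (x axis, B for Basque and LW for Large White, with live weight in kg), for 4 features; the bars beside the points are mean ± SD, with n of 5 at 35 kg and 10 at 145 kg. Feature 11529 parts the breeds without overlap, and feature 15388 is lowest in the Basque pigs of 35 kg, with a mean of -5.65.

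Between live weights in Basque pigs, 2398 features (28.7%) differed, 1153 higher and 1245 lower at 145 kg, with a median absolute log2 difference of 0.52. At least 2-fold differences were found for 148 higher and 118 lower features. Feature 15388 had the largest increase and was 47.0-fold higher at 145 kg (log2 difference 5.56, SE 0.71, limma adjusted p = 3.31e-06), with means of -0.096 ± 1.10 (SD, n = 10) against -5.65 ± 1.37 (SD, n = 5). Another 11 features followed it at r of at least 0.98, so these were not independent measurements. The feature with the largest decrease was lower at 145 kg by a log2 difference of -3.46 (SE 1.04, limma adjusted p = 0.0130), and its call was lost without Basque 35 kg replicate 2 (-2.91), without chip 5 (-2.39) and without the 10 off-centre arrays (-2.67). The balance turned to 1360 higher and 1220 lower with quantile normalization, and to 1250 and 1177 with median centring.

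Between live weights in Large White pigs, 1541 features (18.4%) differed, 715 higher and 826 lower at 145 kg, with a median absolute log2 difference of 0.54. At least 2-fold differences were found for 127 higher and 87 lower features. The largest increase had a log2 difference of 3.59 (SE 0.63, limma adjusted p = 3.19e-04) and the largest decrease one of -2.73 (SE 0.70, limma adjusted p = 0.00731). That increase was in the same feature as the largest increase between breeds at 35 kg. Both differences use the same Large White pigs of 35 kg, so they are not separate results. Feature 15388 was 10.6-fold higher at 145 kg (log2 difference 3.41, SE 0.71, limma adjusted p = 0.00136), with means of -0.38 ± 1.42 (SD, n = 10) against -3.79 ± 1.68 (SD, n = 5). The count fell to 928 with quantile normalization, to 986 with arrays scaled to 1 median absolute deviation and to 993 without the 10 off-centre arrays. The balance turned to 495 higher and 433 lower with quantile normalization, and to 777 and 705 with median centring.

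The 2 breeds shared 480 features higher and 517 lower at 145 kg, against 98.5 and 122.9 for independent lists, and 4 features had opposite signs. Live weight differences in the breeds, again from separate animals, were correlated across features (r = 0.71, jackknife SE over animals 0.053). Over all animals, 36 features were higher and 17 lower in all 20 pigs of 145 kg than in all 10 pigs of 35 kg, where chance gives 5.57e-04 features.

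**Figure D3:**
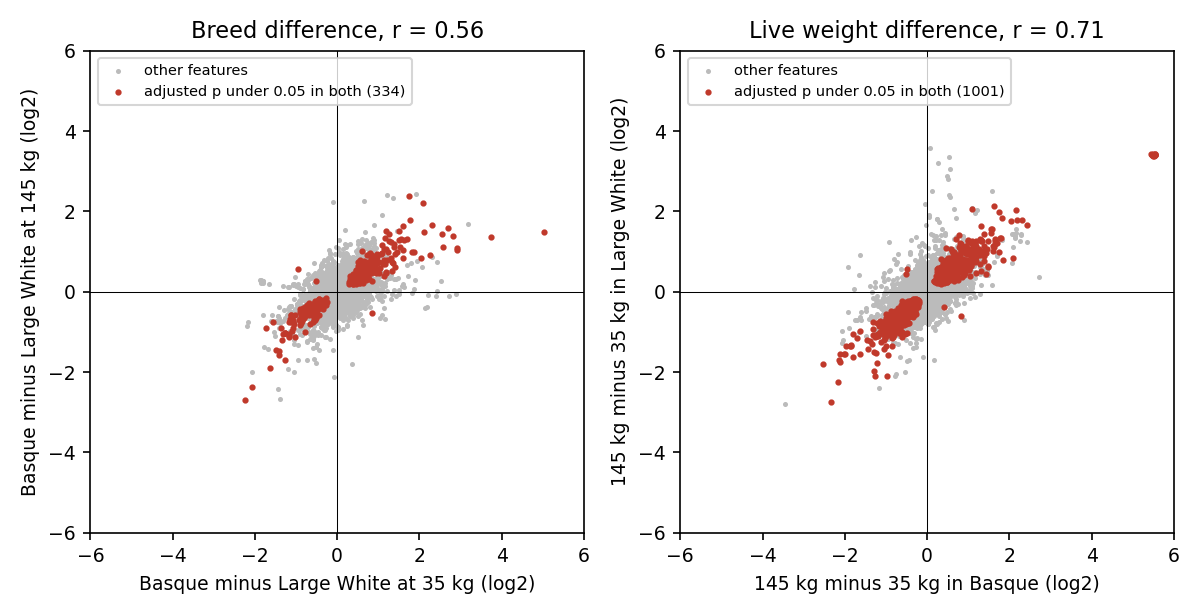
Left, the log2 difference between Basque and Large White pigs at 35 kg (x axis) and 145 kg (y axis); right, the log2 difference between 145 kg and 35 kg in Basque (x axis) and Large White (y axis) pigs, with 1 point per feature and red for an adjusted p under 0.05 in both. The differences are correlated across features (r = 0.56 and r = 0.71).

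The interaction asks whether the breed difference itself changed with live weight, and 19 features passed (12 positive and 7 negative). For 1 of them the limma adjusted p was 0.00914, and for the others it lay between 0.0454 and 0.0499, just under the threshold. At a threshold of 0.01, 1 feature passed. Leaving out 1 animal moved the count by over 1.5 times in 22 of 30 fits. Of the 19, 7 had the same pattern over the groups: their mean was -1.32 ± 0.11 (SD, n = 5) in Basque and -1.39 ± 0.11 (SD, n = 5) in Large White pigs at 35 kg, and 0.37 ± 0.23 (SD, n = 10) and -0.86 ± 0.28 (SD, n = 10) at 145 kg. Their median r over the 30 arrays was 0.90. It includes the group differences for which they were picked, so it does not show that they vary together within a group. With chip as a fixed block 1 feature passed and with chip as a random block 19, with median centring 10, with quantile normalization 8, without chip 5 or the 10 off-centre arrays 0, with array weights 79 (42 positive and 37 negative), and without 1 animal between 1 and 20. All 19 kept their sign with centring and quantile normalization, and the median ratio of their sizes to those above was 0.998 and 1.04; the balance of chips over groups fixes the sizes under the chip block. At an unadjusted p under 0.05, limma gave 929 features.

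Sets of features that varied together were formed from the 400 features with the highest variance within groups, at a correlation distance of 0.3 and with at least 10 features each; these settings were chosen after the data were examined. They gave 5 sets and 20 permutation tests. The correlations were taken over all arrays and so include the group differences. Features may thus share a set because they share a breed or live weight difference, and need not vary together within a group. The permutations kept the sets fixed, so the p-values do not allow for the way the sets were formed. Set 1, with 31 features including feature 15388, was 9.11-fold higher at 145 kg in Basque pigs (exact permutation test, adjusted p = 0.00666) and 4.35-fold higher in Large White pigs (exact permutation test, adjusted p = 0.0266). Set 3, with 15 features, was 2.93-fold lower at 145 kg in Basque (exact permutation test, adjusted p = 0.0266) and 2.11-fold lower in Large White pigs (exact permutation test, adjusted p = 0.0198), and at 145 kg it was 1.99-fold lower in Basque than Large White pigs (permutation test, adjusted p = 0.0198). Set 5, with 11 features, was 6.72-fold higher in Basque than Large White pigs at 35 kg (exact permutation test, adjusted p = 0.0198) and 2.24-fold higher at 145 kg (permutation test, adjusted p = 0.00800), and rose 2.98-fold with live weight in Large White pigs (exact permutation test, adjusted p = 0.0167). Set 4, with 11 features, was 3.59-fold higher in Basque than Large White pigs at 35 kg (exact permutation test, adjusted p = 0.0198), and rose 5.09-fold with live weight in Large White pigs (exact permutation test, adjusted p = 0.00666). Set 2, with 21 features, did not pass in any comparison.

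**Figure D4:**
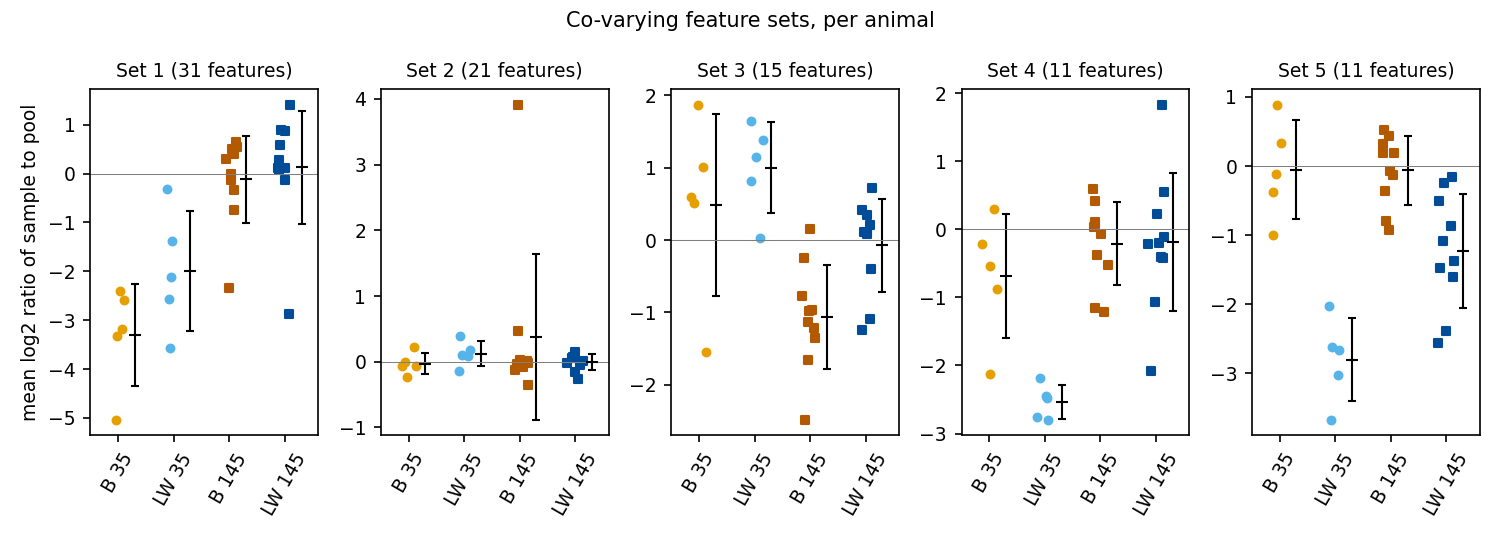
Mean log2 ratio of sample to pool (y axis) of 5 sets of co-varying features in each animal, by group (x axis, B for Basque and LW for Large White, with live weight in kg); the bars beside the points are mean ± SD, with n of 5 at 35 kg and 10 at 145 kg. In set 2 a single Basque pig of 145 kg stands at 3.91, and in set 1 replicate 8 of Large White 145 kg stands at -2.87.

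**Figure D5:**
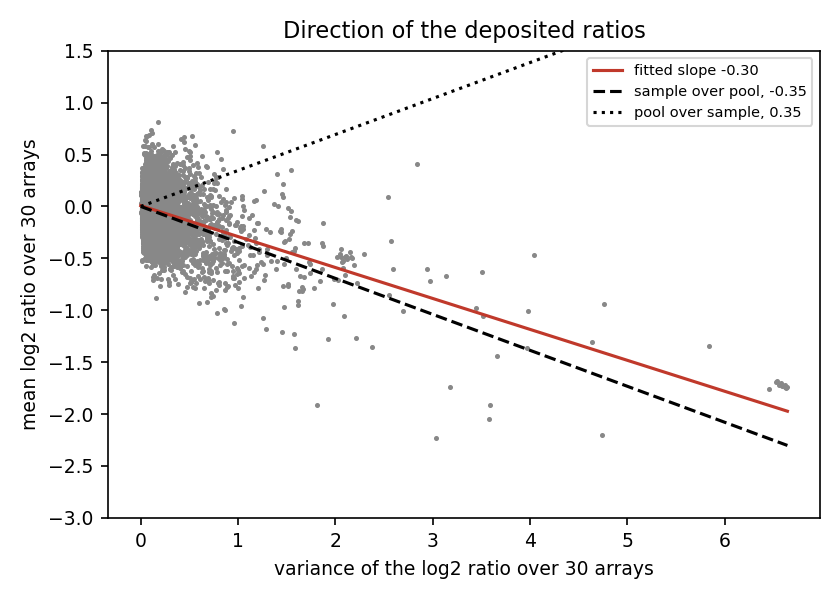
Mean (y axis) against variance (x axis) of the log2 ratio over the 30 arrays, with 1 point per feature. The fitted slope of -0.298 lies near the line for sample over pool (-0.347) and far from the line for pool over sample (0.347).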

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

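The tests on Large White 145 kg replicate 8, the tests of the ratio to the pool, with 6 settings for the features they were compared with, and the noise between Large White pigs were chosen after the results were seen; the splits of the animals and the test of a local blemish were not. The permutation of residuals was added after the splits were seen, with its own outcome unknown. Of 56 groups of values examined for an animal apart from its group, 8 stood out. Chance would give 2.8 for measures not chosen by their values. The sets came from the features that varied most within groups, and feature 15388 is part of set 1, so 2.8 is not the chance value here. The other entry is the 19 features whose breed difference differed between live weights.

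Large White 145 kg replicate 8 lay apart from its group in set 1 (-2.87, the other 9 no lower than -0.13), in feature 11584 (-0.77, next value 0.91) and in feature 15388 (-3.77, next value -0.81). A wrong live weight is argued against by a median position of 1.00 on a scale from -1 at 35 kg to 1 at 145 kg (other 9: 0.648 to 1.47). Noise of single spots is argued against by a correlation of 0.981 within 221 pairs of like features. A fault shared by the whole array or extract could leave that correlation high, so it is not tested by it. A wrong breed and a mixture with Basque RNA stay open, and each was examined in 2 ways. Over 12 features that part the breeds in the other 29 animals, 5 lay nearer the Large White mean, which by the rule set goes with a wrong breed. Left out in the same way, Basque pigs had at most 3 such features nearer the Large White mean, of 6 to 9. The other Large White pigs had at most 28.6% nearer the Basque mean, against 58.3% here. The median share of Basque RNA was 0.546, which by the rule set goes with a mixture (other 9: -0.105 to 0.154). Those 9 had served to choose the 12 features and this animal had not, so their range is no reference for it. In second tests, added because the first had come out so, a median position of 0.0863 lay below all 15 Basque pigs (0.445 to 1.49), which speaks against a wrong breed, but also above the other 14 Large White pigs (-1.33 to -0.553), and 6 of the 12 features still parted the breeds with this animal counted as Large White and 7 with it counted as Basque. For the mixture, 123 features lay beyond all other arrays by over 0.5, where other animals had a median of 16 and up to 285. The share ranged from -0.534 to 1.63 over features. Feature 11529 kept the Large White level, but it was picked for parting the breeds with this animal counted as Large White. No biological explanation was tested.

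Basque 145 kg replicate 1 lay apart in set 2, at 3.91 (15.0-fold over the pool), where the next animal of its group was at 0.47. RNA of the extract is in the pool at 1 part in 30, so the other 29 arrays should lie near 0.516 of the pool at that fold, but the median over the set was 1.05 without this animal and 1.40 with it (near the 1.47 of RNA absent from the pool, so the limit of 1.5 first set for 1.40 decides nothing), and the median share of the needed fall was -0.0213 (-0.560 to 0.625 over features, 1 if kept). Alone these values would speak against RNA of the extract, but -0.0213 lies between the quartiles of the 22 features described next, so they cannot decide. RNA of the extract stays open. Features over 4-fold in 1 other animal kept little of the fall too (median 0.179 for 22 features, quartiles -0.494 and 0.888), though 25 features at a lower bound kept it (1.03, quartiles 0.476 and 2.41). In Basque 145 kg replicate 1, 2 features lay over 30 times the pool, at 51.2 and 361, and no other value of the 30 arrays did. They were picked for exceeding that limit, so their number decides nothing, though 361 lies far above it. A local blemish cannot be told apart either: 39.83% of random sets lay as close in feature number, the bound set beforehand against a blemish, but feature number is not a known position on the array, so that bound was wrong. No biological explanation was tested.

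More features differed with live weight in Basque than in Large White pigs, a gap of 857. Of 100 permutations of breed within live weight, 5 gave a gap as large, the highest other being 1020, so by the rule set chance is not excluded. These are the permutations used below for the interaction, which do not keep the breed effect. They cannot settle whether chance gives such a gap, and residuals of an additive fit were not permuted for it. Greater noise between Large White pigs cannot be told apart from a smaller effect by the test made. The noise-corrected SD of live weight differences was larger in Basque pigs by 0.0699, with a jackknife SE of 0.040. The noise taken off was pooled over all groups and the same in both breeds, so greater noise in 1 breed was not corrected. In the main fit the SE was also the same in both breeds (median 0.160). With the compared groups alone in the fit, the counts were 2581 in Basque and 1191 in Large White pigs. A breed difference in the response stays open.

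Chance could be excluded for the counts of the 4 comparisons: of 100 splits each, the real one included, 1 gave as many features for breed at 145 kg (1467, highest other 57), 1 for breed at 35 kg (728, highest other 102), 1 for live weight in Basque (2398, highest other 715) and 1 for live weight in Large White (1541, highest other 903). For the interaction (19), permuting breed within live weight gave as many in 3 of 100, with a highest other of 269. Such permutations do not keep the breed effect, and the one with 269 gave 14 of 20 animals their own breed at 145 kg and 8 of 10 the other breed at 35 kg, so that the breed difference entered with opposite signs. When the residuals of an additive fit were permuted within live weight, which keeps both effects, 1 of 100 gave as many and the highest other was 3, so chance could be excluded for that count in the fit without chip. The permutation did not keep chips together, and it does not bear on the fall to 1 with chip as a fixed block, to 1 with least squares, or to 0 without chip 5 or without the off-centre arrays (limma; 929 at an unadjusted p under 0.05 with all arrays). Of the other animals apart from their groups, Basque 145 kg replicate 10 lay at -2.34 in set 1 (next -0.74) and at -25.2 on the second component (next -16.2). Basque 145 kg replicate 2 lay at -0.011 in feature 11529 (next -0.86). Basque 35 kg replicate 2 had an array median of -0.0149 (next -0.00300).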

How the results depend on the processing

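Leaving out doubted arrays and the replicate number as a block were chosen after seeing the data; the other alternatives were planned. Counts are given for breed at 145 kg (1467), breed at 35 kg (728), live weight in Basque (2398), live weight in Large White pigs (1541) and the interaction (19), where they moved by over 1.5 times; the cause was not tested unless stated. Quantile normalization gave 424 for breed at 35 kg, 928 for live weight in Large White and 8 for the interaction; scaling to 1 median absolute deviation gave 466, 986 and 8. Median centring gave 10, least squares 1 and chip as a fixed replicate block 1 for the interaction, against 19 with chip as a random block; the chip block moved no other count by over 1.5 times. Array weights gave 1370 for breed at 35 kg and 79 for the interaction. With the features of below-median variance left out, the counts were 752, 331, 1071, 787 and 8, as fewer features entered. An adjusted p of 0.01 gave 687, 257, 1397, 742 and 1, and a fold of at least 1.5 gave 461, 378, 991 and 672 for the 4 comparisons, by construction. Without the 10 off-centre arrays, breed at 145 kg gave 658, live weight in Large White 993 and the interaction 0 (limma; 929 at an unadjusted p under 0.05 with all arrays). Without chip 5 the counts were 907 and 465 for breed at 145 kg and 35 kg and 0 for the interaction. Without both Basque 145 kg replicate 1 and Large White 145 kg replicate 8, the interaction gave 9. The replicate number as a block gave 60 for live weight in Large White, feature 15388 not among them (limma adjusted p = 0.0717), and 5 for the interaction. For live weight, animals of 145 kg without a same-numbered animal at 35 kg drop out under that block, which costs precision by construction. In Basque pigs, with the same layout, it gave 1916. Same-numbered animals did not all deviate together (correlations from -0.192 to 0.311), so the numbers do not pair the animals except where they share a chip. That held for 5 of 5 pairs at 35 kg, 0 of 10 at 145 kg, and between live weights for 3 of 5 in Large White and 1 of 5 in Basque pigs. Leaving out 1 animal gave 1155 to 1805 for breed at 145 kg, 413 to 937 for breed at 35 kg, 1993 to 2563 and 1122 to 1642 for live weight in Basque and Large White, and 1 to 20 for the interaction; the highest of the first 4 came without Large White 145 kg replicate 8. The slope that sets the direction was -0.440 over the 2938 features past the threshold for live weight, with the variance of group means, and -0.307 without Basque 145 kg replicate 1. Of 920 values of the followed features under alternatives, 877 kept their side of the threshold, 32 lost and 11 gained a call, and 0 reversed. Testing each probe alone and requiring complete values changed nothing by construction, and the gene list alternatives were not run for want of gene names.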

Other observations

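Corrected for noise, which raises a correlation by construction, the correlation across features was 0.81 (jackknife SE 0.092) for breed between live weights and 0.90 (jackknife SE 0.057) for live weight between breeds. Features called with 1 chip left out had the same sign in that chip for 71.4% to 95.7% (breed at 145 kg), 86.0% to 96.6% (breed at 35 kg), 84.5% to 96.9% (live weight in Basque) and 88.7% to 95.1% (live weight in Large White). The median SD between animals was 0.31 in Large White pigs of 145 kg, 0.25 in Basque pigs of 145 kg, 0.22 in Basque pigs of 35 kg and 0.23 in Large White pigs of 35 kg.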
